A study of Arabidopsis thaliana with 6 samples.

How the data were processed

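Pollinated flowers of Arabidopsis thaliana at stage 14-15, from plants of the Ler accession, were profiled on Affymetrix ATH1 GeneChips, which carry several short probes (a probe set) per transcript. The 6 arrays were each hybridised with biotin-labelled cRNA made from total RNA, per the labels' protocols. Group and replicate number came from the sample titles, which name 3 biological replicates of pop2-1 homozygous flowers and 3 of wild-type flowers. Some free-text fields of the wild-type samples repeat the mutant's wording, so those fields were not used for grouping.

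The deposited values were MAS5 signals, 1 linear hybridisation intensity per probe set and array, made with MAS5 per the submitters' processing notes. MAS5 subtracts a local background, combines the perfect-match and mismatch probes of a probe set and scales each array to a common average. The version and the target of the scaling were not given in the sources used here. In the deposited values the 2% trimmed mean was 500.04 on each of the 6 arrays. A common average hides any change in total RNA per flower, so all differences are relative to the average probe set. Detection calls were not used here, so a low signal is not known to lie above background. The number of arrays limits the precision of every value.

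Gene names came from the platform annotation of the probe sets, updated through the Entrez gene number to the reference gene table of assembly TAIR10.1. Of 22810 probe sets, 64 were array controls. The annotation gave 1 gene for 13513 probe sets and several genes for 503, and 8794 were not listed. The reference table held 13436 of the 13513. Probe sets with several genes or no listed gene were tested and counted but not named. A probe set whose table entry is a locus number is called by that number. POP2 itself and the other genes of the GABA shunt were among the genes without a listed probe set, so the level of the mutated gene was not analysed here and could not be set against the labels. Coordinates are not given because no genome build accompanies the signals.

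A pseudocount of 16 was added to each signal and log2 was taken, so a fold change is on the log2(signal + 16) scale and understates the change of dim transcripts. Probe sets at or below the 40th percentile of the mean over all 6 arrays, a signal of about 126, were not tested. This left 13647 of 22746 probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment over all probe sets tested. A probe set at an adjusted p under 0.05 is said to have risen or fallen in pop2-1. Errors beside log2 differences are limma's standard errors. Signals are given as mean ± SD over 3 arrays.

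Before the data were examined, 36 gene lists were fixed, covering metabolic pathways, cell wall families, floral cell types, hormones and stress responses. Members were matched by symbol, synonym or locus, and 2 members whose symbol and locus pointed to different genes were left out. The pectin, class III peroxidase, histone and ribosomal protein lists had been fixed as patterns on the gene description. They were instead matched on symbols and synonyms, so they were not run as fixed, and the peroxidase list held 0 genes. In 26 lists at least 1 gene was named on the array, often a small part of the list. Named were 4 of 17 flavonoid genes, 2 of 12 for senescence and 4 of 22 for sucrose and starch. For pollen 7 of 27 were named, and for auxin 12 of 121. A result for a list therefore covers its tested genes and not the whole pathway. Lists with at least 5 tested genes, 8 in all, were tested with limma's camera at a preset correlation of 0.01, using the brightest probe set of each gene. A camera test with an estimated correlation and limma's fry were run beside it. For every list, the number of genes passing when p-values were adjusted over the list alone was also taken.

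The rule for named genes was fixed at the same time. POP2 was to be given first. Then came up to 12 largest rises and 12 largest falls among the probe sets that passed, each with 1 named gene and with all 3 pop2-1 signals beyond all 3 wild-type signals. From each list described, up to 4 members with the smallest p were added, and all tested genes of the GABA shunt, of which there were none. Genes named outside this rule are marked as chosen after their values were seen.

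Both groups carry replicate numbers 1 to 3. The deviations of same-numbered arrays from their group means correlated at 0.213, 0.421 and 0.178 across probe sets, and 6 of 6 arrays correlated best with the array of the same number in the other group. Deviations were centred within groups of 3, so these 6 matches are not independent of one another. The numbers were treated as a possible pairing, and calls come from the fit without it unless the block is named. The pairing comes from the titles' numbers and these correlations; no label states what a number shares. Values with the replicate number as a block are given beside the results that they change.

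RNA quality was read from the array controls as the ratio of 3' to 5' probe set signals of actin, GAPDH and ubiquitin transcripts. On data simulated from these arrays, with 200 changed probe sets among 13647 in each of 10 data sets, 20.6% of the probe sets shifted by 0.5 on the log2 scale were called, 93.6% of those shifted by 1, 99.2% of those shifted by 1.5 and 100% of those shifted by 2, and 6.73% of calls were false. A simulated list shifted by 0.5 was called in 20 of 20 simulations over 7240 genes, with 3 calls of other lists in total. The simulated noise was independent between probe sets, with no correlation between genes, no pairing and no array of poor quality. These rates therefore hold for that simpler case and may be better than those of the real arrays.

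The alternatives tried were quantile normalization, scaling to equal medians, other pseudocounts and filters, limma without trend, with robust variances or with array weights, a per-probe-set unequal-variance test, other thresholds, leaving out probe sets that can match several transcripts, the replicate block, and leaving out each array in turn. After the data had been seen, the 3'/5' ratio as a covariate and leaving out pair 2 under the block were added.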

Results

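The series compared flowers of the pop2-1 mutant with those of the wild type to find which transcripts differ where endogenous GABA is high. POP2 encodes the transaminase that breaks down γ-aminobutyric acid (GABA), and its loss raises GABA in the flower. Each group had 3 arrays of pollinated flowers, 6 in all. Median signals lay between 209.3 and 228.9, and signals ran from 0.0659 to 25468.6. Spearman correlations across tested probe sets were 0.929 to 0.96 between pop2-1 arrays and 0.979 to 0.982 between wild-type arrays, computed across transcripts that are not independent replicates. The POP2 transcript was not analysed here.

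The largest rise in pop2-1 flowers was that of BSMT1, the methyltransferase that makes volatile methyl benzoate and methyl salicylate. Its signal was 627 ± 58.3 in pop2-1 and 157 ± 26.4 in wild type (SD, n = 3 per group), a 3.73-fold difference (log2 1.90 ± 0.16, limma adjusted p = 0.00205). AT5G18840, a member of the sugar transporter family, rose 3.59-fold, from 450 ± 42.6 to 1654 ± 59.9 (SD, n = 3 per group, limma adjusted p = 0.000607). OCT1, an organic cation and carnitine transporter, rose 3.17-fold, from 750 ± 93.8 to 2409 ± 274 (SD, n = 3 per group, limma adjusted p = 0.00205). The glutaredoxin genes AT2G30540 and AT1G06830 rose by 1.57 and 1.01 on the log2 scale.

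The other named rises were smaller than that of OCT1. AT2G45180, of the protease inhibitor and lipid transfer protein superfamily, rose 2.83-fold, and AT5G37170 rose by 0.99 on the log2 scale. AT2G30150, a UDP-glycosyltransferase gene, rose by 0.89, TBL26, of the TRICHOME BIREFRINGENCE-LIKE family, by 0.82, AT4G32340 by 0.76 and AT5G08350 by 0.71. Limma adjusted p over the 11 named rises ran from 0.000607 for AT5G18840 to 0.0488 for AT5G08350. In each of the 11 genes all 3 pop2-1 signals exceeded all 3 wild-type signals, which the rule for named genes required. The probe sets with no listed gene held 9 of the rises, the largest 1.27 on the log2 scale.

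The largest fall was that of AT4G15750, of the invertase and pectin methylesterase inhibitor superfamily, which was 5.83-fold lower in pop2-1 (421 ± 185 against 2454 ± 610, SD, n = 3 per group; limma adjusted p = 0.0079). BAN, the anthocyanidin reductase of proanthocyanidin synthesis in the seed coat, was 5.47-fold lower, at 56.2 ± 14.0 in pop2-1 and 394 ± 144 in wild type (SD, n = 3 per group, limma adjusted p = 0.0102). The pop2-1 signals of BAN lay below the level of 126 used to leave out dim probe sets, so its fold depends on the pseudocount. The same limit holds for AT1G54790, RALFL18 and AT5MAT, described below, whose 3 pop2-1 signals also lay under that level. DFR, the dihydroflavonol reductase that both anthocyanins and proanthocyanidins need, fell from 887 ± 168 to 280 ± 96.4 (SD, n = 3 per group), 3.13-fold (limma adjusted p = 0.017). UF3GT, an anthocyanin glycosyltransferase gene, fell 2.53-fold (log2 -1.34, limma adjusted p = 0.00691) and AT4G14090, the anthocyanin 5-O-glucosyltransferase gene, 2.59-fold (log2 -1.37, limma adjusted p = 0.0079); neither is on the fixed flavonoid list.

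AT5G47350 fell by 2.31 on the log2 scale and AT5G01870, a lipid transfer protein gene, by 1.74. The cytochrome P450 gene CYP71B23 and AT4G16000 each fell by 1.46. AT1G54790, a GDSL lipase gene, fell by 1.28, and the chitinase family gene AT2G43620 fell by 1.17. The aspartic protease gene AT4G04460 was 2.29-fold lower. Limma adjusted p over these 12 largest falls ran from 0.00691 for UF3GT to 0.0488 for AT4G04460. The other falls with 1 named gene were smaller, and their genes were named after the values were seen. They were RALFL18, a signalling peptide of the RALF family (log2 -1.04), the homeodomain-leucine zipper factor HAT2 (-0.92), AT4G00700 (-0.87), AT1G13470 (-0.86), AT1G72230 (-0.85), the GDSL lipase gene AT5G45670 (-0.81), AT3G60420 (-0.81), the chaperone gene Hsp70-2 (-0.72) and AT1G49050 (-0.67). HAT2 varied little within groups, with signals of 461 to 471 in pop2-1 and 856 to 935 in wild type (n = 3 per group). Probe sets with no listed gene held 21 of the falls, the largest -1.90 on the log2 scale.

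**Figure D1:**
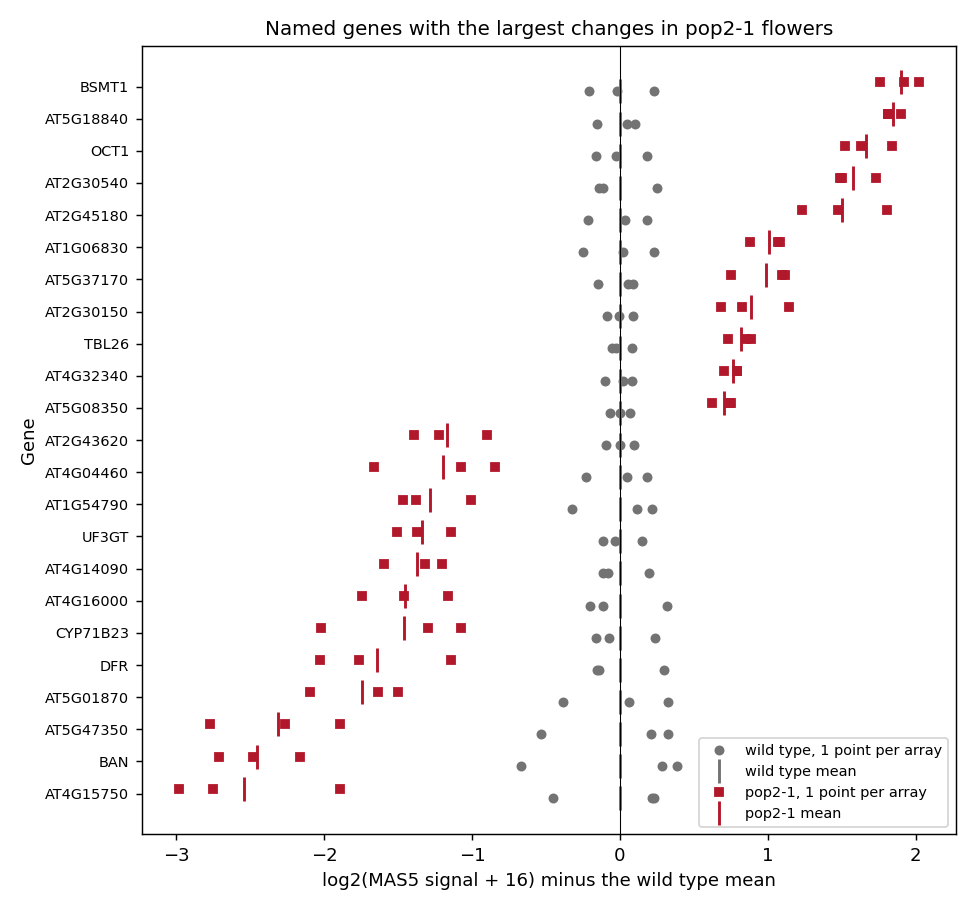
Signal of the 23 genes with the largest rises and falls, as log2(MAS5 signal + 16) minus the wild-type mean of the gene, on the horizontal axis, with genes on the vertical axis. Each grey circle is a wild-type array, each red square a pop2-1 array and each red bar a pop2-1 mean (n = 3 per group), and in every gene shown the 3 squares lie on one side of the 3 circles, from BSMT1 at 1.90 to AT4G15750 at -2.54.

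In all, 63 of 13647 probe sets changed, with 20 higher and 43 lower in pop2-1. The higher set named 11 genes, and the lower set named 21. In each of the 63 the groups did not overlap, which held for 17.9% of all tested probe sets where chance gives 10%. Passing the threshold with 3 arrays per group favours this, so for the 63 it is no separate support. At least a 2-fold difference was found in 11 of the rises and 30 of the falls. At an unadjusted p under 0.05 there were 1621 probe sets where 682 would pass by chance. With the replicate number as a block, 257 probe sets changed, 108 higher and 149 lower, and these held all 63. Leaving out 1 array gave 496 calls without pop2-1 replicate 1 and 5 without pop2-1 replicate 3. Without pop2-1 replicate 2 there were 75 calls, which held 53 of the 63. There were 14 without wild-type replicate 1, 5 without wild-type replicate 2 and 8 without wild-type replicate 3. BSMT1, AT5G18840, OCT1 and 1 probe set with no listed gene were the 4 called in all 6 fits that leave out 1 array, while BAN was called in 3, UF3GT in 4, AT4G14090 in 3 and DFR in 2. Array weights gave 946 calls, a filter at the 60th percentile gave 37 and no filter gave 42. A per-probe-set unequal-variance test gave 0, with 1017 at an unadjusted p under 0.05. That test shares no variance between probe sets. With 3 arrays per group it has little power after adjustment over 13647 probe sets, so its 0 does not count against the calls.

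Of the 4 tested genes of the flavonoid and anthocyanin list, DFR fell and 3 did not pass. With p-values adjusted over the list alone, 2 passed, DFR and AT5MAT, an anthocyanin malonyltransferase gene (log2 -0.79 ± 0.16, limma adjusted p = 0.0871 over all probe sets). UGT78D2, a flavonoid 3-O-glucosyltransferase gene that acts on anthocyanidins as well as flavonols, had a log2 difference of -0.13 ± 0.13 (limma adjusted p = 0.727), and the flavonol glycosyltransferase gene UGT78D1 one of 0.23 ± 0.16. In the young seed list, BAN fell and was the 1 gene bright enough to test, so adjustment over the list alone adds nothing there. Of the 19 genes on that list 3 were named on the array, and the other named genes, AGL62 and IKU2, were too dim.

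Of the 3 tested genes for nectary and floral scent, BSMT1 rose and 2 did not pass, and BSMT1 was the 1 gene passing when adjusted over the list alone. The terpene synthase gene AT3G25810 had a log2 difference of 0.36 ± 0.18 (limma adjusted p = 0.461). SWEET9, the sugar exporter of nectaries, had one of -0.01 ± 0.08, with signals of 7117 ± 264 in pop2-1 and 7148 ± 190 in wild type (SD, n = 3 per group); its sign changed with quantile normalization, to 0.05. In the heat shock list Hsp70-2 fell, over the list alone as well, and the other tested gene did not pass; that gene, BRK1, is a regulator of actin matched through an old synonym.

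No sucrose and starch gene of 4 passed over all probe sets, and 3 passed when adjusted over the list alone. These were AMY1, an α-amylase gene (log2 -0.65 ± 0.14, limma adjusted p = 0.0961), DPE1, a glucanotransferase gene (0.36 ± 0.13, 0.309), and APL3, a subunit of ADP-glucose pyrophosphorylase (0.61 ± 0.22, 0.327). SBE2.2, a starch branching enzyme gene, had a log2 difference of 0.17 ± 0.12. Both senescence genes tested, SAG29 (log2 -0.65 ± 0.22) and WRKY6 (-0.43 ± 0.19), passed when adjusted over the list alone and not over all probe sets (limma adjusted p = 0.298 and 0.413). Both were lowest on pop2-1 replicate 2, the array with the highest actin 3'/5' ratio, and without it they stood at -0.39 and -0.27 and 0 of 2 passed over the list alone. The loss was not particular to that array. Without pop2-1 replicate 3, wild-type replicate 1 or wild-type replicate 3, 0 of 2 passed, and without wild-type replicate 2 only SAG29 did. Both passed without pop2-1 replicate 1. Of the sucrose and starch genes AMY1 passed over the list alone in all 6 fits that leave out 1 array, and DPE1 and APL3 in 2. In the pistil and ovule list 0 of 3 genes passed in limma either way and 0 had an unadjusted p under 0.05, with INO, an ovule integument gene, at 0.31 ± 0.20 and ALC, a fruit opening gene, at -0.22 ± 0.13. The 3 named tapetum genes were too dim to test.

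Of the 8 lists tested as sets, 0 passed with camera after adjustment and 2 had an unadjusted p under 0.05. With an estimated correlation, and with fry, 0 had an unadjusted p under 0.05. The pollen and pollen tube list was higher in pop2-1 for 5 of its 6 tested genes (mean log2 0.37, camera p = 0.0186, adjusted p = 0.0942, adjusted p = 0.569 with an estimated correlation). With the replicate block its camera adjusted p was 0.0206. It was 0.0342 after quantile normalization and 0.0477 after scaling to equal medians, within a range of 0.0192 to 0.569 over all alternatives. In limma 0 of its genes passed over all probe sets or over the list alone, and 2 had an unadjusted p under 0.05. MGH3, a histone of male gametes, had a log2 difference of 0.53 ± 0.23, the pollen tube receptor kinase ANX2 one of 0.49 ± 0.24, and the related kinases AT2G21480 and AT4G39110 had 0.49 ± 0.22 and 0.42 ± 0.22.

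The array of pop2-1 replicate 2 stood apart in RNA quality, with an actin 3'/5' signal ratio of 9.73 against 1.72 to 2.93 on the other 5 arrays. The same array had the highest signals of ANX2 (741), AT4G39110 (950) and MGH3 (309), and wild-type replicate 2 had the highest wild-type signals of these genes (368, 642 and 195). AT2G21480 (206) and ACT12 (225), an actin gene of pollen chosen after its values were seen, were highest on pop2-1 replicate 3. Without pop2-1 replicate 2 the mean of the pollen list was 0.25 (camera adjusted p = 0.24). With both arrays of pair 2 left out under the replicate block, also chosen after the data had been seen, it was 0.32 (camera adjusted p = 0.0339). The camera adjusted p was 0.0192 without pop2-1 replicate 1, 0.0347 without wild-type replicate 2 and 0.0458 without wild-type replicate 3, but 0.163 without pop2-1 replicate 3 and 0.202 without wild-type replicate 1. With the 3'/5' ratio as a covariate, an alternative chosen after the data had been seen, that mean was 0.24 (camera adjusted p = 0.248), and limma called 154 probe sets that held all 63.

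**Figure D2:**
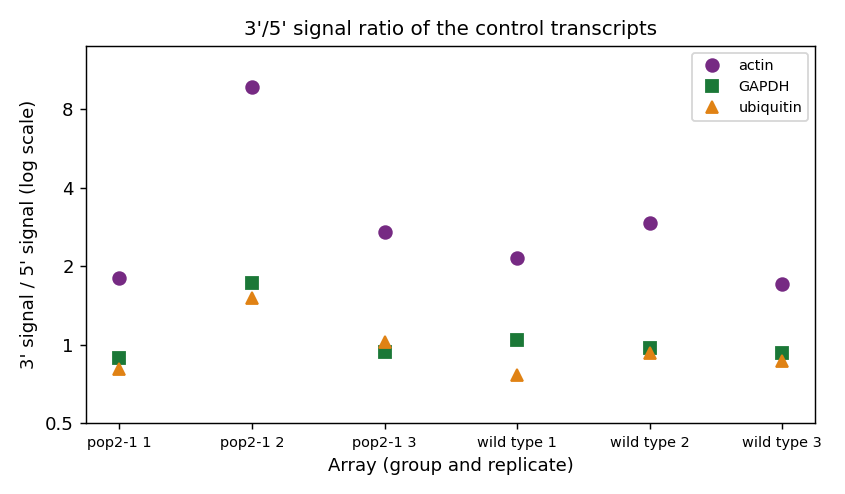
Ratio of 3' to 5' control signals on a log scale for actin, GAPDH and ubiquitin transcripts on each of the 6 arrays, 1 point per control and array. Actin reached 9.73, GAPDH 1.73 and ubiquitin 1.51 on pop2-1 replicate 2, each the highest of the 6 arrays.

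The photosynthesis list was higher in pop2-1 for 21 of 28 genes (mean log2 0.21, camera p = 0.0236, adjusted p = 0.0942, adjusted p = 0.569 with an estimated correlation). Its plastid-encoded and nuclear members went different ways, a difference that was not tested. Of 20 plastid-encoded genes 19 were higher, with a median log2 difference of 0.36. Of 8 nuclear genes 2 were higher, with a median of -0.12. The members with the smallest p were psbF (log2 0.50 ± 0.13), psbJ (0.64 ± 0.18), psbE (0.38 ± 0.13) and psbZ (0.44 ± 0.18), all plastid-encoded subunits of photosystem II, and 0 genes of the list passed in limma over all probe sets or over the list alone, with 4 at an unadjusted p under 0.05. With the replicate block psbJ passed (limma adjusted p = 0.0437, 0.188 without). The camera adjusted p of the list was 0.00473 after quantile normalization, 0.0477 after scaling to equal medians, 0.0199 with a filter at the 60th percentile and 0.0197 with the 3'/5' covariate, within a range of 8.74e-05 to 0.68 over all alternatives. It was 0.0116 without pop2-1 replicate 2, 0.00331 without wild-type replicate 2 and 0.0458 without wild-type replicate 3, but 0.68 without pop2-1 replicate 1, 0.0842 without pop2-1 replicate 3 and 0.644 without wild-type replicate 1. Without wild-type replicate 1, the array with the lowest mean of plastid-encoded transcripts, the mean of the list was 0.08 in place of 0.21.

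Auxin response genes had a mean log2 difference of -0.23 over 5 tested members (camera adjusted p = 0.169, adjusted p = 0.569 with an estimated correlation). With no filter the list held 12 genes, 7 of them too dim for the test above, and its camera adjusted p was 0.038, within 0.038 to 0.609 over all alternatives. Without pop2-1 replicate 2, on which GH3.17 (679) and IAA18 (585) were lowest, the mean was -0.12. The amido synthetase gene GH3.17, at -0.71 ± 0.21, was the 1 member passing over the list alone, which held in 1 of the 6 fits that leave out 1 array, and IAA18 stood at -0.43 ± 0.15. Expansins had a mean of -0.07 over 9 members (camera adjusted p = 0.169), with EXPA15 at -0.25 ± 0.10 and EXPB3 at -0.22 ± 0.10. Xyloglucan endotransglucosylase/hydrolase genes differed in both directions, with a camera adjusted p of 0.732 over 6 members. XTH33 (log2 0.79 ± 0.18) and XTH29 (-0.60 ± 0.20) were the 2 that passed over the list alone, and 0 passed without pop2-1 replicate 3 or without wild-type replicate 3. The cellulose synthase family (mean 0.19 over 8 genes), the TCA cycle and organic acid list (-0.06 over 6) and the glutathione transferases (-0.03 over 7) had camera adjusted p of 0.206, 0.414 and 0.859, and 0 of their 21 members passed in limma over all probe sets or over the list alone, with 2 at an unadjusted p under 0.05. The remaining 10 lists with tested genes covered proline, pectin, wall proteins, lignin, salicylic acid, jasmonate, abscisic acid and cold, antioxidants, ethylene and histones. The genes matched to the wall protein list, PRP39 and PEX4, act in RNA processing and in peroxisomes, so no wall protein of that list was tested. Of the 18 tested genes of these 10 lists 0 passed in limma either way. An unadjusted p under 0.05 was found for 4, among them MGH3, also a member of the pollen list. The salicylic acid, jasmonate, ethylene, antioxidant and lignin lists had 1 tested gene each, of 17, 24, 14, 14 and 16 genes fixed. These pathways were therefore hardly tested.

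**Figure D3:**
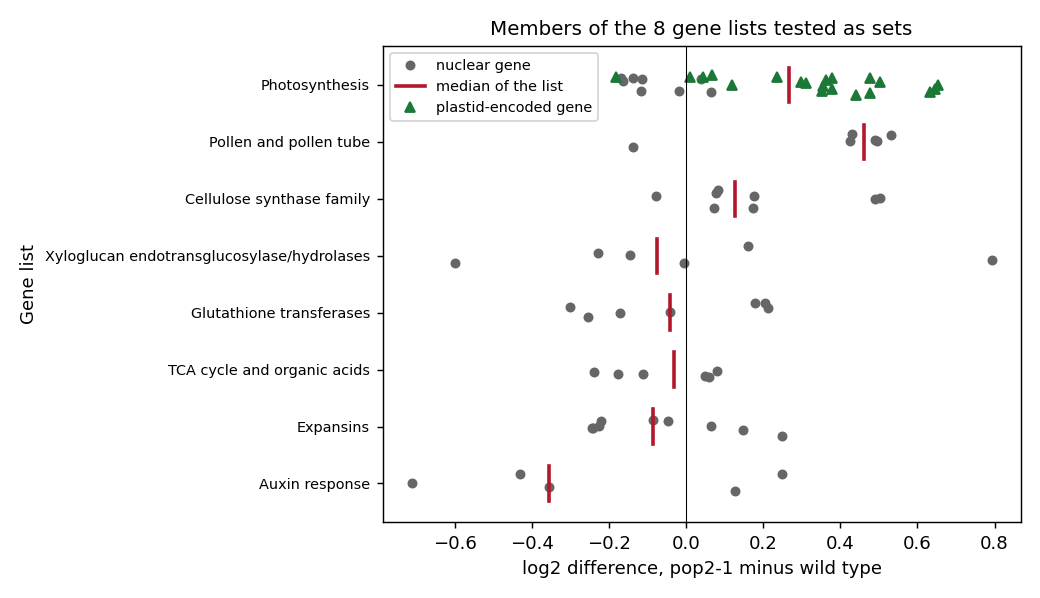
Log2 difference, pop2-1 minus wild type, of each tested gene of the 8 lists tested as sets, 1 point per gene, with the list median as a red bar. Green triangles mark plastid-encoded genes, 19 of 20 of which lie above 0, and grey circles mark nuclear genes.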

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

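The alternatives with the 3'/5' covariate and with pair 2 left out were chosen after the data had been seen; the rest were planned. The counts of calls moved with several settings. None of the 32 named genes that passed changed direction under any, but their groups did not overlap, so leaving out an array could not have reversed them. Where a count moved by over 1.5 times, the cause was not tested unless a smaller set of arrays or genes gives it. A filter at the 60th percentile gave 13 rises and 24 falls from fewer genes tested, and no filter gave 27 falls. Array weights gave 464 rises and 482 falls, an adjusted p under 0.10 gave 65 and 85, and the per-probe-set unequal-variance test gave 0 and 0. Requiring a 2-fold difference left 11 rises. The replicate block gave 108 rises and 149 falls and called 1 list, the pollen list, as higher, a list whose adjusted p without the block was 0.569 with an estimated correlation and 0.24 without pop2-1 replicate 2. The block changed no other list's call, and none of the 63 calls was lost. The 3'/5' covariate gave 66 rises and 88 falls, and pair 2 left out, with the replicate block, gave 8 and 7. Leaving out 1 array gave 3 to 190 rises, 2 to 306 falls and 0 to 2 lists higher. Of the 32 named genes, 32 were called without pop2-1 replicate 1, 28 without pop2-1 replicate 2, 4 without pop2-1 replicate 3, 9 without wild-type replicate 1, 3 without wild-type replicate 2 and 6 without wild-type replicate 3. Quantile normalization, scaling to equal medians, an adjusted p under 0.10 and pair 2 left out with the block each called 2 lists higher. The filter at the 60th percentile and the 3'/5' covariate each called 1, and no filter called 1 list lower.

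Reversals were seen in SWEET9 and in 2 lists that did not pass under any setting. SWEET9 stood at 0.0537 after quantile normalization and at 0.0146 with array weights, and ran from -0.0244 to 0.0246 when 1 array was left out. The xyloglucan endotransglucosylase/hydrolase mean was 0.17 with array weights, 0.0602 with the 3'/5' covariate and 0.0653 with pair 2 left out. It ran from -0.123 to 0.0903 when 1 array was left out. The glutathione transferase mean was 0.0592 with the filter at the 60th percentile, 0.0366 with array weights, 0.0841 with the covariate and 0.0741 with pair 2 left out. It ran from -0.11 to 0.0986 when 1 array was left out, and fry gave its direction as higher at a mean of -0.0257. Signals near background limit the folds of dim transcripts such as BAN, and detection calls were not used here.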

Other observations

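The genes named in the first paragraph, the anthocyanin genes, BAN, and the tests on organelle transcripts, on gene position and with the 3'/5' covariate were chosen after values had been seen. With the replicate number as a block, 194 further probe sets passed, 88 higher and 106 lower in pop2-1. Of these, 25 named a gene by a symbol, 20 higher and 5 lower, and 7 of the 20 are encoded in plastids or mitochondria. GI, a clock component, was 1.89-fold higher (1008 ± 71.9 against 537 ± 135, SD, n = 3 per group; limma adjusted p = 0.021 with the block and 0.0765 without). BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, was 2.46-fold higher (limma adjusted p = 0.022 with the block, 0.123 without). The jasmonate response factor MYC3 differed by 0.60 on the log2 scale, the sugar transporter gene SWEET10 by 0.63 and the lectin gene JAL23 by 1.31. Among the lower genes were MSRB5, a methionine sulfoxide reductase gene (log2 -1.39), the β-glucosidase gene BGLU28 (-1.03) and the cytochrome P450 gene CYP71B38 (-1.02).

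Of the 10 splits of the 6 arrays into 3 and 3, the real one called 63 probe sets and the highest of the others 0, so 1 split reached the count. With the block, the real one called 257 and the highest of the others 0 among the 4 splits that part all pairs, so 1 split reached it. In both cases the splits are too few for a share under 0.05.

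Most plastid- and mitochondrion-encoded probe sets had a higher mean in pop2-1, but neither group passed a test over arrays. Of 65 plastid-encoded probe sets 64 were higher, with a median log2 difference of 0.38 (exact permutation test of the array means, 2-sided, p = 0.2). All 9 mitochondrion-encoded probe sets were higher (p = 0.1 in the same exact test, the smallest that 3 arrays against 3 allow). Their mean was higher in all 3 pairs, by 0.63, 0.42 and 0.52 on the log2 scale (exact sign-flip test, p = 0.25, the smallest that 3 pairs allow). In limma 0 passed singly, with 21 plastid and 6 mitochondrial probe sets at an unadjusted p under 0.05, and 6 plastid and 1 mitochondrial probe sets passed with the block, among them psbJ (log2 0.64), ccsA (0.75), rpoC2 (0.74) and cox1 (0.81). After quantile normalization 63 of the plastid and 8 of the mitochondrial probe sets were higher, and after scaling to equal medians 60 and 8.

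Wild-type replicate 1 had the lowest plastid mean, and without it the plastid median was 0.24 in place of 0.38. The remaining wild-type arrays had plastid means of 10.75 and 10.45, against 10.83, 10.88 and 10.75 in pop2-1, so the groups touched. That array carried part of the observed difference, and whether the rest exceeds the spread between arrays was not tested. A candidate explanation is unequal carry-over of RNA without poly(A) tails. It predicts a rise in mitochondrial transcripts, whose median was 0.526 (standard error 0.115 across genes), and in the 25S rRNA control, which was added to the test after its values had been seen. That control went the other way and was lower in pop2-1 in all 3 pairs, by -1.81, -0.53 and -1.19 on the log2 scale, while the plastid mean was higher in all 3 pairs, by 0.69, 0.13 and 0.30. The 25S signals of the groups overlapped, at 459.7 to 996.5 in pop2-1 and 821.7 to 3505 in wild type (exact 2-sided permutation test, p = 0.2). The highest was that of wild-type replicate 1, the array with the lowest plastid mean. These values go against the prediction but come from 1 control, and 3 pairs cannot give an exact 2-sided p below 0.25. Carry-over and a change in organelle transcripts in the mutant therefore cannot be told apart.

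The mean log2 difference of DFR, UF3GT and AT4G14090 was -1.45, and at its smallest -1.41 when 1 pop2-1 array was left out. On these arrays the difference was thus not in a single pop2-1 array. The genes were picked for groups that do not overlap, which favours this outcome, so it is no separate test and says nothing of other samples. With the 3'/5' ratio of the controls as a covariate the mean was -1.43, and all 3 genes passed (highest limma adjusted p = 0.0137). That ratio stood apart on pop2-1 replicate 2 alone, so the fit comes close to leaving that array out, where the mean was -1.41. It therefore bears on that array only and cannot decide whether RNA quality on the others is part of the source. That the lower transcripts belong to the pop2-1 genotype, or to a difference in growth between the plants collected, remains a hypothesis that these arrays leave untested.

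For BAN, a candidate explanation is fewer fertilised ovules or younger seeds in pop2-1 flowers. It predicts that the other young seed genes are lower too, but 0 of them were tested, so it stays open. Of the 19 genes on that list 3 were named on the array, and AGL62 and IKU2 were too dim. The rest had no probe set with 1 listed gene, so their level is not known. The log2 difference of BAN itself ran from -2.79 to -1.88 over the alternatives.

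Taken over the whole genome, the named called genes did not lie closer together than random draws of tested genes. The 32 named called genes formed 15 pairs lying within 200 named array genes of each other, against a median of 15 in 10000 random draws of tested genes (permutation p = 0.527, one-sided). The 95th percentile of the draws was 22 pairs, so a segment with few called genes could have gone unseen. Called probe sets without 1 named gene were not part of the test. Chromosomes 1 to 5 held 7, 5, 3, 7 and 10 of the 32 genes, among 1887, 1040, 1488, 1032 and 1728 tested genes.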
